A study of Mus musculus with 6 samples.

How the data were processed

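The study measured RNA in abdominal adipose tissue of C57BL/6 mice 6 times, on 3 arrays from mice that had a duodenal-jejunal bypass (DJB) and 3 from mice that had a sham operation. Per the labels' protocols, the mice were given a high-fat diet from 6 weeks of age and were randomised to surgery after 12 weeks on it. Per the labels' protocols, total RNA was extracted, amplified and labelled with cyanine 3 by a low-input whole-transcript kit, so each array has 1 colour. Per the file headers, the arrays were scanned and quantified by the authors with Agilent Feature Extraction 12.0.3.1 under the protocol GE1_1200_Jun14, and the header's genome build field reads mm9.

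Each deposited scanner file gives, per spot, a processed intensity on a linear scale that Feature Extraction had background-subtracted and detrended, without scaling between arrays. The deposited mean spot intensity, the local background intensity and the flags for spots well above background, saturated or outlying were also used. The authors also deposited a table of log2 values with a column for each array. Against the scanner files, each of its columns correlated best with its own array (Pearson r of at least 0.99934 over 150305 matched probes of 150373 listed). Its medians lay between 4.546 and 4.558, and its sorted columns differed by at most 0.122, as columns do after quantile normalization. The direction follows from these correlations and the table is not centred per gene. The design text of the series describes a different experiment and was not used. limma is named in the submitters' processing notes without a version or a role.

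The header of each file announces 172336 features and the files hold 155279, and the other 17057 were not analysed here. Of these features 150305 were probes other than controls, each spotted once. By the form of their identifiers, 47074 were named by a RefSeq mRNA, 1393 by a RefSeq non-coding RNA, 55674 by a NONCODE transcript (a catalogue of long non-coding RNAs), 8299 by an Ensembl transcript, 37852 by a genomic interval with a strand, and 13 in another way. The interval form is one used for circular RNAs, but the files give no transcript class, so the identifier type was used in its place and no probe is called circular here. The build of these intervals is not stated. Of the 37852 intervals, 98.2% lay inside a gene of the GRCm38.p6 gene table, against 43.4% and 42.1% after moving them by 500000 and -500000 bases. Their coordinates were therefore read as GRCm38. Gene symbols came from that table by accession for 46711 mRNA and 1337 non-coding RefSeq probes, and otherwise from the files. NONCODE, Ensembl and interval-named probes were reported by identifier.

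All computation used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The log2 of the processed intensity was taken, and each array's 75th percentile over all non-control probes was subtracted. Spots with an outlier flag, 18 to 25 per array, were set to missing, and no probe was saturated. A probe was tested if it was well above background on at least 3 of the 6 arrays, whichever those were, which left 99420 probes. DJB was compared with Sham by limma's moderated test (lmFit and eBayes, two-sided, no covariates, prior degrees of freedom 2.26), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Every adjusted p of a probe or gene in the text is from this fit unless another is named, and every difference is DJB minus Sham on the log2 scale. A looser set, at least 2-fold with an unadjusted p under 0.05, is not corrected for multiple tests.

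For genes, the tested probe with the highest mean signal over all 6 arrays stood for each symbol, which gave 18315 genes. Where a probe was not well above background on any array of a group, the difference is a bound: the brighter group's mean was set against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Such differences are written as "at least" so many fold.

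The gene lists, 32 in number with 561 distinct symbols (of which Faim3 and Fcmr name the same gene), were fixed before the data were examined. So were the settings of the comparison, the rule for naming genes and all alternatives except 1. They cover fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, lipolysis and lipid droplet, fatty acid oxidation, thermogenic and beige adipocyte, oxidative phosphorylation, mature adipocyte and adipokines, insulin signalling and glucose use, incretin and bile acid receptors, inflammatory cytokines and chemokines, interferon response, extracellular matrix and fibrosis, endoplasmic reticulum stress, hypoxia response, immediate early genes and tissue handling, circadian clock, cell cycle and glucocorticoid response. The others hold markers of cells or neighbouring tissues that a fat sample can hold, namely macrophage, T and NK cell, B cell and plasma cell, neutrophil and mast cell, dendritic cell and antigen presentation, adipocyte progenitor and fibroblast, endothelial cell, mesothelial cell, pancreatic acinar cell, epididymis and testis, liver, skeletal muscle, intestinal epithelium and smooth muscle, and red blood cell. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists, and beside it with an estimated correlation per list and with fry, which tests whether a list's genes move one way on balance without comparing them with other genes. A list's score on an array is the median over members of the array's value minus the mean of the 6 arrays.

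Genes were named by a fixed rule: the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between groups, then up to 4 members with the smallest unadjusted p from each called list and up to 2 from each other list; 18 genes of adipose metabolism and inflammation in every case; and, with the identifier type taken in place of a class once the files had shown none, the 3 highest and 3 lowest called probes of each non-coding identifier type. Other genes are named only to describe a list's members or where the text says that they were chosen after their values were seen.

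The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, a percentile over probes detected on all arrays, the authors' log2 table, 3 other filters on dim probes, a trended robust prior, array weights, the slide as a block, the replicate number as a block, leaving out each array, the mean of all tested probes of a gene, and adjustment within each probe type. A fit on slide 1 alone was added after seeing the data. The fit was tested on simulated data built from the means and spreads of 99404 probes at 3 arrays per group. It called 6% of 100 probes changed 2-fold and 82% of 100 probes changed 4-fold, 7 unchanged probes and none in the wrong direction, and it called 0 probes when nothing was changed. Only 200 of the 99404 probes were changed, so the adjusted threshold was harder to pass than in the real comparison, which called 4967 probes. The 6% and 82% are therefore not the sensitivity of the real comparison. All 4 lists lowered 2-fold in simulated arrays were called. The simulated probes were drawn independently of each other, so the list test was not tried on genes that move together. Control spots were left out, and no sample was left out of the main comparison.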

Results

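RNA from abdominal adipose tissue of C57BL/6 mice fed a high-fat diet was measured after duodenal-jejunal bypass (DJB) or a sham operation, with n = 3 arrays per group. In the bypass the biliopancreatic limb was 5 cm and the Roux limb 4 cm long. The labels do not say that the arrays came from separate animals, so the p-values measure the spread between these samples. With 3 against 3 arrays an exact permutation test cannot go below 0.10, and having 3 arrays per group limited the precision. The labels also give neither the fat depot within the abdomen nor the time after surgery. The 75th percentile of signal was 183.3, 175.8 and 183.7 on the Sham arrays and 165.3, 145.6 and 132.0 on the DJB arrays. Of the probes, 64.7% to 68.8% on Sham and 62.6% to 64.9% on DJB arrays were well above background.

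Several genes of lipid synthesis were lower in the adipose tissue of DJB mice than in that of Sham mice, as were some markers of muscle, liver and mesothelium. Fasn, the fatty acid synthase, fell by 2.29 on the log2 scale (SE 0.15, adjusted p = 0.00660), although not all of its tested probes were lower (their range is given below). Dgat2, an enzyme of the last step of triglyceride synthesis, fell by 3.07 (SE 0.28, adjusted p = 0.0125), and Lep, which encodes leptin, fell by 2.96 (SE 0.55, 0.0435). H2-Eb1, a class II antigen-presenting molecule, fell by 1.60 (SE 0.12, 0.00805). S100a9, a calcium-binding protein of neutrophils and monocytes, rose by 2.86 (SE 0.45, 0.0340), and Mmp12, the macrophage elastase, by 1.63 (SE 0.21, 0.0261). Adipoq, which encodes adiponectin, was not called (-1.12, SE 0.35, 0.108), nor was Ucp1 (-0.94, SE 1.499, 0.717).

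Of 18315 named genes, 257 rose and 1117 fell, so 81.3% of the 1374 called genes were lower in DJB. Over all 99420 tested probes, 1830 were called higher and 3137 lower, and the median log2 difference was 0.080. This excess of lower probes depended on the choices made. With normexp background correction 7011 were called higher and 4901 lower, and lower calls were 51.5% with median scaling and 50.2% with a trended robust prior. Of the called genes at least 66.3% were lower in every alternative that called any. Among genes with an unadjusted p under 0.05 in limma's test, however, 3566 of 6509 were higher with median scaling, against 2455 of 6142 in the main fit. The looser set of probes, at least 2-fold with an unadjusted p under 0.05 and without correction, held 867 higher and 5113 lower. In all, 28060 probes had an unadjusted p under 0.05 where 4971 would be expected by chance. The 3 DJB arrays lay wholly on one side of the 3 Sham arrays for 35852 probes (36.1%, against 10% by chance). Leaving out 1 array left 1 higher and 118 lower probes without Sham-1, 21 and 314 without Sham-2, and 396 and 2727 without Sham-3. It left 106 and 728 without DJB-1, 5 and 188 without DJB-2, and 790 and 3181 without DJB-3. The called genes, 1374 with all arrays, numbered 44 without Sham-1, 130 without Sham-2, 1215 without Sham-3, 295 without DJB-1, 66 without DJB-2 and 1081 without DJB-3. The arrays lay on 2 slides, with 2 of each group on slide 1 and 1 of each on slide 2. With the slide as a block 88 probes were called higher and 619 lower, and 12 genes higher and 223 lower.

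Correlations between arrays over the tested probes ranged from 0.973 to 0.989 within a group and from 0.944 to 0.980 between groups. Sham-3 correlated best with an array of the other group, DJB-3 (0.9800, against 0.9734 with Sham-1 and 0.9794 with Sham-2). The first principal component carried 57.7% of the variance and placed the Sham arrays at -156.1, -114.6 and -15.7 and the DJB arrays at 141.6, 100.6 and 44.1.

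Among the called genes that did not overlap between the groups, the 10 falls named by the fixed rule began with Trdn (triadin, of the muscle calcium release complex; -6.43, SE 0.64, adjusted p = 0.0160) and Tph2 (a tryptophan hydroxylase of serotonin synthesis; -6.39, SE 0.27, 0.00229). They also took in 6 major urinary protein genes, Plppr4 (at least 29.9-fold lower, 0.00660) and Mogat2 (a monoacylglycerol acyltransferase; -4.87, SE 0.24, 0.00373). The urinary protein genes are close paralogs, so their probes cannot be assigned with certainty. They were Mup16 (-6.25), Mup9 (-5.94), Mup2 (-5.72), Mup15 (-5.56), Mup1 (-5.51) and Mup17 (at least 38.7-fold lower, 0.0101). Trdn, Mup16, Mup15 and Mup1 were well above background on 1 of 3 DJB arrays and Mup2 on 2. The 10 rises were Stfa2l1 (3.15, SE 0.51, 0.0353), S100a9, P4ha3 (2.75, SE 0.52, 0.0444), Ptprn (2.11, SE 0.43, 0.04995) and Npy, which encodes neuropeptide Y (2.09, SE 0.30, 0.0298). They also included Bst1 (2.04, SE 0.34, 0.0377), Cd207, which encodes langerin (1.77, SE 0.28, 0.0346), Mmp12, Olfr711 (at least 1.44-fold, 0.0206) and Gm9758 (1.57, SE 0.31, 0.0460). Stfa2l1 and Gm9758 were well above background on 1 of 3 Sham arrays and Cd207 on 2. Where a fold is given as a bound, no array of the dimmer group was well above background, so its rank among these genes is not known. The bound was taken with the brighter group's mean set against the mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Of 73 called named genes, 11 stayed called without Sham-1, 17 without Sham-2, 35 without Sham-3, 23 without DJB-1, 9 without DJB-2 and 52 without DJB-3. Tph2, Mup17, Plppr4, Mogat2, Fasn, Acta2, H2-Eb1 and Pvalb stayed called in each of these 6 fits. With the slide as a block 24 of the 73 stayed called, among them all 10 falls named above but, of the 10 rises, only Mmp12 and Olfr711. The others then had adjusted p = 0.0614 for Stfa2l1, 0.0688 for P4ha3, 0.0808 for Ptprn, 0.0604 for Npy, 0.0644 for Bst1, 0.0653 for Cd207 and 0.0561 for Gm9758. The differences stayed as they were, since the slides are balanced between the groups. Other calls kept with this block were those of Fasn, Scd2, Dgat2, Pnpla3, Hilpda, H2-Eb1, Ciita, Acta2, Serpina1a, Alb, Pvalb and Casq1, and the rest of the 73 lost theirs. With the block Tph2 had an adjusted p of 0.0153 (-6.73 on slide 1, -5.71 on slide 2), Fasn 0.0194 (-2.37 and -2.13) and H2-Eb1 0.0245 (-1.53 and -1.75). The blocked adjusted p was for Mmp12 0.0457 (1.74 and 1.40), S100a9 0.0581 (2.20 and 4.18) and Lep 0.0675 (-3.65 and -1.58).

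**Figure D1:**
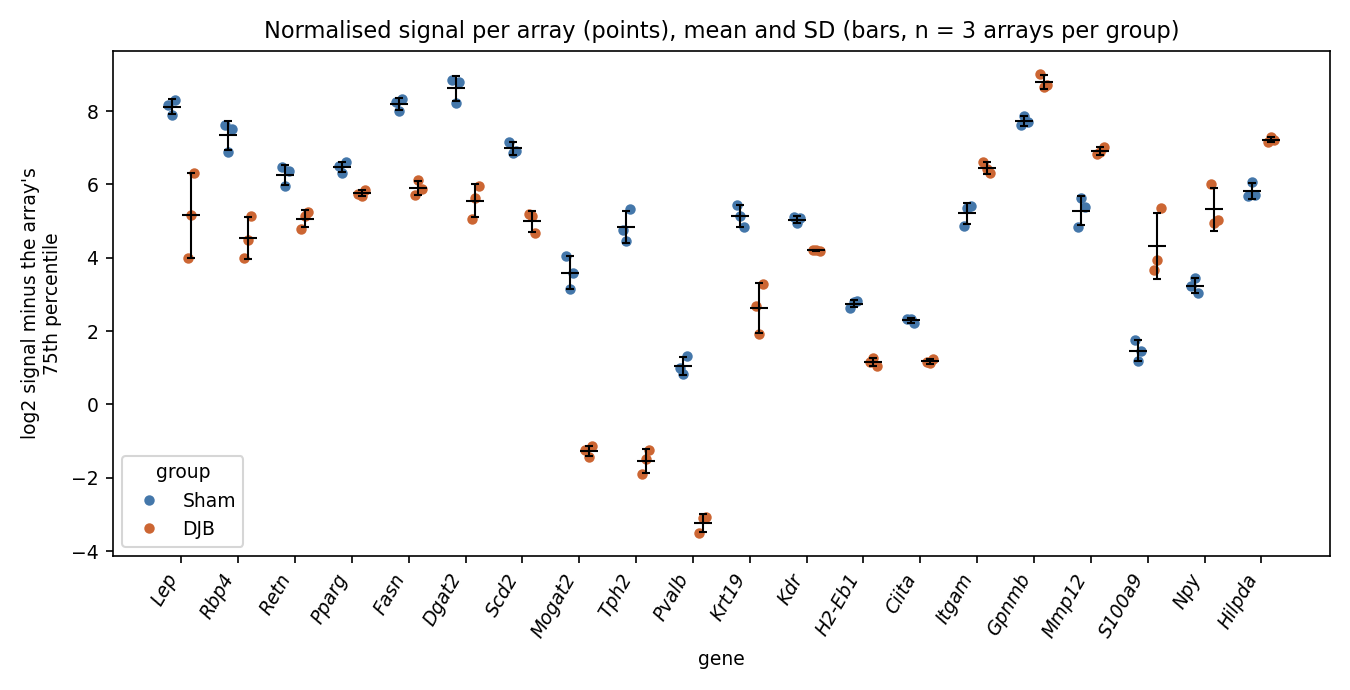
Log2 signal of 20 called genes on each array, relative to the array's 75th percentile (points), with the mean and SD of each group (n = 3). The genes shown were chosen after their values were seen.

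Genes of fatty acid and triglyceride synthesis were lower as a group. Of 21 tested, 9 fell and none rose, and 16 fell when adjusted over the list alone (median -1.13, camera adjusted p = 1.56e-06, adjusted p = 0.510 with an estimated correlation). Beside Fasn and Dgat2, the falls were of Pnpla3 (-3.75, SE 0.42, adjusted p = 0.0206), Scd2 (-1.99, 0.0125), Thrsp (-2.09), Agpat2 (-1.76), Fads2 (-1.30), Acaca (-0.91) and Srebf1 (-0.73), whereas Scd1 was not called (-1.38, SE 0.50, 0.143). Of 18 mature adipocyte and adipokine genes 5 fell, and adjusted over the list alone 9 fell and 1 rose (median -0.59, 0.00349, adjusted p = 0.525 with an estimated correlation). The falls were those of Lep, Mest (-3.41, SE 0.48, 0.0286), Rbp4 (-2.80, SE 0.33, 0.0225), Retn, which encodes resistin (-1.20, SE 0.19, 0.0348), and Pparg, the regulator of adipocyte differentiation (-0.72, SE 0.12, 0.0376). Among the others Fabp4 differed by 0.078, Lpl by -0.083 and Cd36 by 0.42. The lipolysis and lipid droplet list was lower (16 tested, median -1.16, camera adjusted p = 0.0350, adjusted p = 0.634 with an estimated correlation). Mgll fell (-1.15) but the droplet genes Hilpda (1.40, SE 0.14, 0.0173) and Plin2 (0.69, SE 0.12, 0.0377) rose, and 10 were lower and 3 higher adjusted over the list alone. Lipe (-1.18, 0.141) and Pnpla2 (-0.23, 0.553), which encode the hormone-sensitive and adipose triglyceride lipases, were not called. This list's call was lost without Sham-1 (median -1.06, 0.0707) and without Sham-3 (-1.14, 0.0880). In the same comparison the macrophage list was higher, and the mesothelial (median -1.60), endothelial (-0.48) and red blood cell (-0.99) lists were lower. For each of these 4 lists the adjusted p = 0.510 with an estimated correlation.

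Of 18 genes of fatty acid oxidation 3 fell, Decr1 (-1.01, SE 0.16), Cpt1b (-0.99, SE 0.17) and Acadm (-0.71, SE 0.14). Adjusted over the list alone 10 fell (median -0.55, camera adjusted p = 0.000629, adjusted p = 0.510 with an estimated correlation). The thermogenic and beige adipocyte list was lower (19 tested, median -0.94, 0.00384, adjusted p = 0.510 with an estimated correlation). Otop1 (-2.05, SE 0.36) and Cox7a1 (-0.90, SE 0.18) fell, and there were 8 lower and 1 higher adjusted over the list alone. Oxidative phosphorylation was not called (23 tested, none called, also over the list alone; median -0.13, adjusted p = 0.232, and adjusted p = 0.634 with an estimated correlation). It was past the threshold with normexp (-0.19, 0.00763), quantile normalization (-0.25, 0.00109) and the authors' values (-0.28, 0.000959). The insulin signalling and glucose use list was lower (20 tested, median -0.53, 0.0257, adjusted p = 0.618 with an estimated correlation). Its members were mixed. Irs1, an insulin receptor substrate, fell (-0.75, SE 0.15), the glucose transporter Slc2a1 (1.10, SE 0.17) and the phosphatase Ptpn1 (0.87, SE 0.18) rose, and adjusted over the list alone 10 fell and 3 rose. Slc2a4, the insulin-regulated glucose transporter, differed by -1.92 (SE 0.54, 0.0881) and Pck1 by -0.84 (SE 0.37, 0.196). The insulin list's call was lost without Sham-3 (median -0.53, 0.0915) and with the mean of probes (-0.49, 0.0527). The incretin and bile acid receptor list was not called (13 tested, median -0.21, adjusted p = 0.248, and adjusted p = 0.634 with an estimated correlation). Gipr, the receptor of the incretin GIP, fell by 1.77 (SE 0.25, 0.0286), and over the list alone 1 rose and 2 fell. The cholesterol synthesis and uptake list was not called either (18 tested, median 0.27, adjusted p = 0.193, and adjusted p = 0.682 with an estimated correlation). Nsdhl (-0.65) and Hmgcs1 (-0.89) fell and Cyp51 rose (0.69), with 7 higher and 4 lower adjusted over the list alone.

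**Figure D2:**
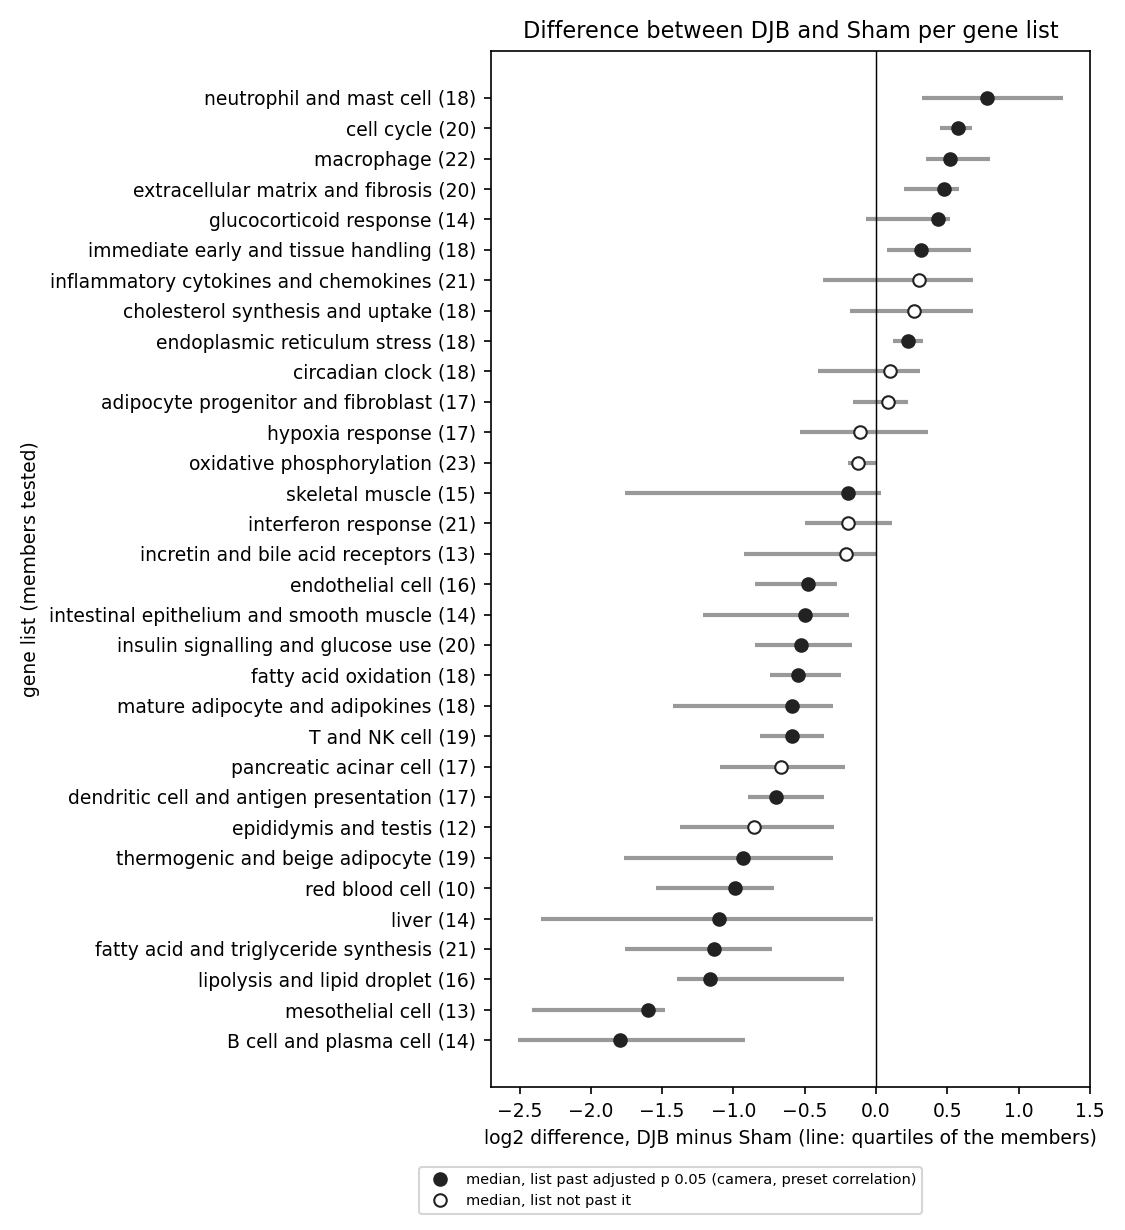
Median log2 difference, DJB minus Sham, of each gene list (points) with the quartiles of its members (lines). Filled points mark lists past the threshold by camera with the preset correlation.

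The macrophage list was higher. Of its genes 3 of 22 rose and none fell, 9 rose adjusted over the list alone, and 21 of 22 had a positive value (median 0.52, camera adjusted p = 1.02e-05, adjusted p = 0.510 with an estimated correlation). The risen genes were Mmp12, Gpnmb (1.06, SE 0.15, adjusted p = 0.0282) and the integrin Itgam (1.23, SE 0.18, 0.0306). Not called were Adgre1, which encodes F4/80 (0.34, SE 0.23, 0.374), Itgax (0.46, SE 0.29, 0.344) and Trem2 (0.67, SE 0.19, 0.0868). The neutrophil and mast cell list was higher (18 tested, median 0.78, 0.00189, adjusted p = 0.510 with an estimated correlation), with S100a9 called and 3 higher adjusted over the list alone. Dendritic cell and antigen presentation genes were lower. The 6 of 17 that fell were H2-Eb1, Ciita, the class II transactivator (-1.11, SE 0.10, 0.0135), H2-Aa (-0.90), H2-Ab1 (-0.85), H2-DMb1 (-0.82) and H2-DMa (-0.76). Adjusted over the list alone 8 fell and 1 rose (median -0.71, 0.000148, adjusted p = 0.318 with an estimated correlation). The T and NK cell list (19 tested, median -0.59, 0.00626, adjusted p = 0.525 with an estimated correlation) and the B cell and plasma cell list (14 tested, median -1.80, 0.00313, adjusted p = 0.525 with an estimated correlation) were lower without a called gene. Adjusted over the list alone 6 T and NK cell genes and no B cell gene were lower. B cell scores overlapped between Sham (1.09, 1.75 and -0.072) and DJB (-1.64, -1.21 and 0.28). The inflammatory cytokine and chemokine list was not called (21 tested, median 0.30, adjusted p = 0.232, and adjusted p = 0.686 with an estimated correlation), but was past the threshold without DJB-1 (0.54, 0.0475), and without DJB-2 its median was -0.083. Of its genes, Ccl2 (0.68, SE 0.14, 0.0488), Ccl3 (1.24, SE 0.25) and Tlr4 (0.67, SE 0.13) rose. Il6 (1.49, SE 1.02, 0.380) and Tnf (-0.16, SE 0.43, 0.835) were not called, and 4 rose and 3 fell adjusted over the list alone. The interferon list was not called and held no called gene, also over the list alone (21 tested, median -0.20, adjusted p = 0.424, and adjusted p = 0.811 with an estimated correlation), but was past the threshold without DJB-1 (-0.61, 0.000353), and its median was 0.19 without DJB-2 and 0.12 on slide 1.

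Among lists of the stroma, extracellular matrix and fibrosis genes were higher (20 tested, median 0.47, camera adjusted p = 0.00626, adjusted p = 0.525 with an estimated correlation). Its 1 called gene, Acta2, the smooth muscle actin, fell by 2.40 (SE 0.14, adjusted p = 0.00554). The list's call was lost with quantile normalization (median 0.28, 0.0571) and the authors' values (0.28, 0.0708). Adjusted over the list alone 6 rose and 2 fell, and the collagen gene Col1a1 was not called (0.64, SE 0.19, 0.0960). The 4 probes of Acta2 ranged from -3.22 to 0.066 and the 3 of Fasn from -3.30 to 0.40. The adipocyte progenitor and fibroblast list was not called (17 tested, median 0.083, mean -0.019, test direction up, adjusted p = 0.424, and adjusted p = 0.737 with an estimated correlation) and had no called gene, with 1 higher and 1 lower adjusted over the list alone. Endothelial genes were lower (16 tested, median -0.48, 0.00189, adjusted p = 0.510 with an estimated correlation). Kdr, a receptor for vascular endothelial growth factor (-0.83, SE 0.10), and Prox1, a regulator of lymphatic endothelium (-1.16, SE 0.20), fell, and 7 were lower adjusted over the list alone. Mesothelial genes were lower in all 13 values (median -1.60, 0.000269, adjusted p = 0.510 with an estimated correlation). Krt19 (-2.51, SE 0.36) and Rspo1 (-1.77, SE 0.30) fell, and 11 were lower adjusted over the list alone.

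Markers of neighbouring tissues also moved with the groups. Of 15 skeletal muscle genes 6 fell, among them Acta1 (-4.77, SE 0.65), Pvalb (-4.28, SE 0.19, adjusted p = 0.00229), Casq1 (-1.91), Myh2 (-1.61) and Tnnc2 (-1.49). Adjusted over the list alone 7 fell, with a median of -0.20 and a mean of -1.19 (camera adjusted p = 0.0112, adjusted p = 0.510 with an estimated correlation). Of 14 liver genes 4 fell, Alb, which encodes albumin (-2.89, SE 0.38, 0.0262), Serpina1a (-2.44), Serpina3k (-2.07) and Hpx (-1.07). Adjusted over the list alone 7 fell (median -1.10, 0.00734, adjusted p = 0.510 with an estimated correlation). The liver list's call was lost with normexp (median -0.36, 0.0698). In the intestinal epithelium and smooth muscle list Cnn1 (-2.61, SE 0.52) and Myh11 (-2.10, SE 0.31), both of smooth muscle, fell. In this list 9 of 14 fell adjusted over the list alone (median -0.50, 0.00765, adjusted p = 0.525 with an estimated correlation). Red blood cell genes were lower in all 10 values without a call, and 8 fell adjusted over the list alone (median -0.99, 0.00162, adjusted p = 0.510 with an estimated correlation). The pancreatic acinar list (17 tested, median -0.67, adjusted p = 0.193, and adjusted p = 0.749 with an estimated correlation) and the epididymis and testis list (12 tested, median -0.86, adjusted p = 0.241, and adjusted p = 0.686 with an estimated correlation) were not called and held no called gene, also over the list alone. The acinar list was past the threshold without Sham-2 (-1.11, 0.00429) without DJB-2 (-0.98, 0.0332) and on slide 1 (-0.92, 0.0160), and its median was 0.087 without Sham-1. So was the epididymis and testis list without Sham-3 (-1.65, 0.00320).

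Cell cycle genes were higher. Aurkb (0.76, SE 0.15, adjusted p = 0.0471) and Plk1 (0.81, SE 0.16, 0.0486), kinases of mitosis, rose. Of the 20 genes, 16 rose adjusted over the list alone (median 0.57, camera adjusted p = 1.32e-05, adjusted p = 0.510 with an estimated correlation). The immediate early and tissue handling list was higher with rises of Dusp1 (1.35, SE 0.24), Junb (0.88, SE 0.18) and Zfp36 (0.80, SE 0.16), which were also the 3 of 18 higher over the list alone (median 0.32, 0.00734, adjusted p = 0.525 with an estimated correlation). The endoplasmic reticulum stress list was higher without a called gene, also over the list alone (18 tested, median 0.23, 0.00510, adjusted p = 0.510 with an estimated correlation). Its call was lost with quantile normalization (0.12, 0.0649) and the authors' values (0.12, 0.0805). The glucocorticoid list was higher (14 tested, median 0.43, mean 0.044, 0.0242, adjusted p = 0.525 with an estimated correlation), with Dusp1 called and 4 higher over the list alone, and its call was lost without DJB-3 (median 0.35, 0.149), with median scaling (0.54, 0.0656) and on slide 1 (0.27, 0.194). The circadian list was not called (18 tested, median 0.098, mean -0.095, test direction up, adjusted p = 0.386, and adjusted p = 0.634 with an estimated correlation). Bhlhe41 rose (0.84, SE 0.10), with 1 higher and 1 lower over the list alone. Nor was the hypoxia list (17 tested, median -0.11, adjusted p = 0.759, and adjusted p = 0.782 with an estimated correlation). Of its genes Slc2a1 rose and Pfkfb3 (-1.56, SE 0.27) and Egln3 (-1.37, SE 0.27) fell, with 3 higher and 3 lower over the list alone. In total camera called 22 of 32 lists, 15 lower and 7 higher. Of these, fry called 5 lower, namely fatty acid and triglyceride synthesis (adjusted p = 0.0203), fatty acid oxidation (0.0494), dendritic cell and antigen presentation (0.00141), liver (0.0245) and skeletal muscle (0.00811). With the slide as a block 22 lists were past the threshold. The medians on slide 1 and slide 2 were -1.48 and -0.71 for fatty acid synthesis, 0.63 and 0.40 for macrophage genes and -0.52 and -0.79 for antigen presentation. Some called lists were much smaller on slide 2, among them endothelial (-0.68 and -0.12), mesothelial (-2.12 and -0.54), mature adipocyte (-0.75 and -0.22) and cell cycle genes (0.76 and 0.23). So were lipolysis (-1.54 and -0.39), insulin signalling (-0.70 and -0.19), red blood cell (-1.28 and -0.37) and extracellular matrix genes (0.58 and 0.20). Like antigen presentation, the T and NK cell, skeletal muscle, glucocorticoid and neutrophil lists were instead larger in size on slide 2.

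**Figure D3:**
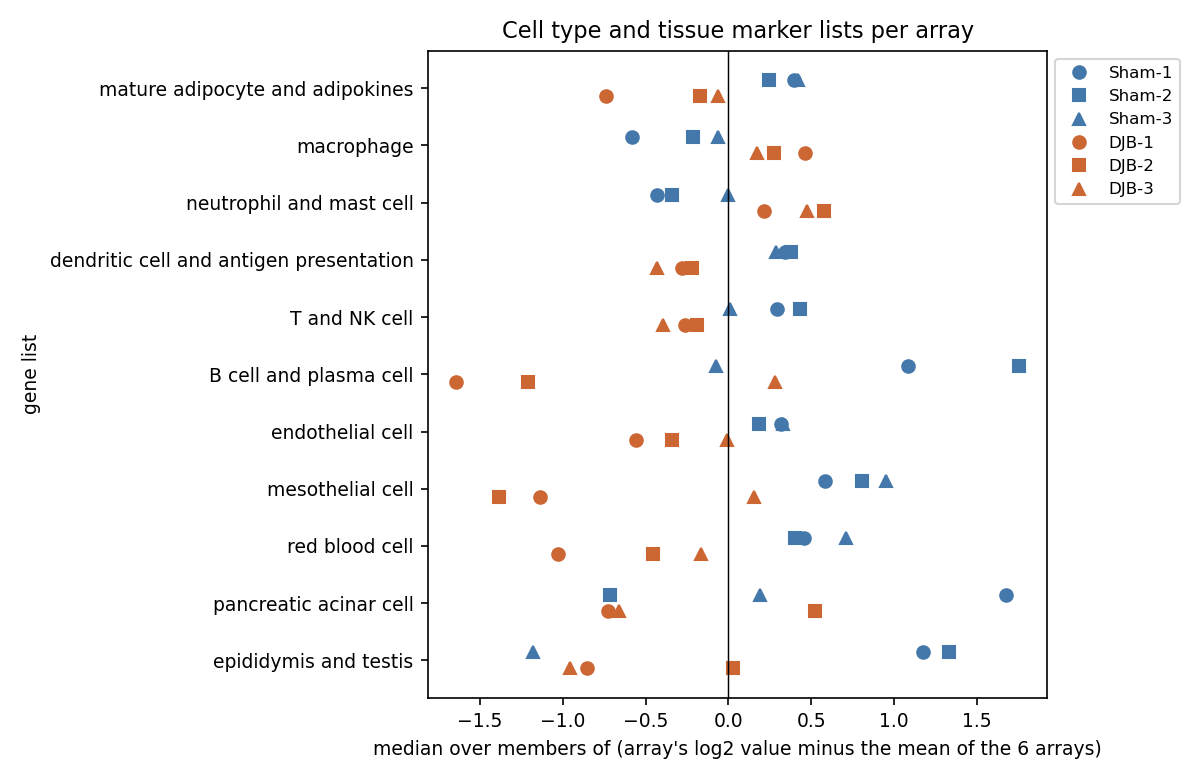
Score of 11 lists of cell type and tissue markers on each array. The score is the median over members of the array's log2 value minus the mean of the 6 arrays.

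At the adjusted threshold the direction of the calls differed between probe types, but this did not hold in all settings. RefSeq mRNA probes were mostly called lower (756 higher, 2046 lower of 39522), as were NONCODE (152 and 491 of 22767), Ensembl transcript (27 and 193 of 4342) and RefSeq non-coding probes (8 and 67 of 829). With normexp NONCODE calls were instead mostly higher (1028 and 399) and Ensembl calls near even (156 and 170), and RefSeq non-coding calls stayed mostly lower (35 and 71). Probes named by a genomic interval were mostly called higher (886 and 340 of 31951). In the looser set, however, they were mostly lower (190 and 597), as were the 4 types above, and limma's test adjusted within this type called 0 higher and 14 lower. The median log2 difference was 0.033 for mRNA, 0.063 for NONCODE, -0.027 for Ensembl, -0.081 for RefSeq non-coding and 0.15 for interval-named probes. The 2 negative signs did not hold, since the Ensembl and RefSeq non-coding medians were 0.112 and 0.058 with normexp and 0.079 and 0.024 with median scaling. The Ensembl median was also above 0 with quantile normalization (0.044), the authors' values (0.041), no filter (0.056), array weights (0.015) and on slide 1 (0.045), and without Sham-3 (0.001) or DJB-3 (0.056). The NONCODE median was -0.007 without DJB-2. Without 1 array the interval-named calls were 0 higher and 8 lower without Sham-1 (5619 with an unadjusted p under 0.05 in limma's test), 4 and 20 without Sham-2, and 168 and 195 without Sham-3. They were 35 and 54 without DJB-1, 4 and 16 without DJB-2, and 302 and 584 without DJB-3. Lower calls thus outnumbered higher ones among interval-named probes in each of these 6 fits, and also with the slide as a block (34 higher, 44 lower), so the excess of higher calls was lost without any 1 array and with this block. The shift itself stayed: the interval-named median exceeded that of mRNA by 0.12 with all arrays and with the block, and by 0.11 to 0.13 without 1 array. At an unadjusted p under 0.05, 6931 of 9183 interval-named probes were higher, 4201 of 5619 without Sham-1 and 6203 of 7917 without DJB-2.

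Among NONCODE transcripts, NONMMUT115571 (2.11, SE 0.18, adjusted p = 0.0118), NONMMUT113221 (at least 2.18-fold, 0.0335) and NONMMUT086365 (1.70, SE 0.19, 0.0206) rose. NONMMUT105352 (at least 11.8-fold, 0.00229), NONMMUT004270 (at least 8.85-fold, 0.0486) and NONMMUT104471 (at least 8.50-fold, 0.0125) fell. Of RefSeq non-coding transcripts, those of Adamtsl5 (1.39, SE 0.20), 1810013A23Rik (1.18, SE 0.21) and 5730416F02Rik (1.05, SE 0.21) rose. Gm5627 (-3.19, SE 0.53), Gm5577 (at least 2.33-fold) and an unnamed transcript (-3.51, SE 0.72, on 1 of 3 DJB arrays) fell. Of the 3 interval-named falls, 1 lay on chromosome 10 at 33139074 to 33158278, inside Trdn (at least 17.5-fold lower, adjusted p = 0.000139). The other 2 lay inside Trhde on the same chromosome, at 114696011 to 114788215 (at least 4.24-fold, 0.0183) and 114444679 to 114448387 (at least 2.72-fold, 0.00229). The 3 rises were on chromosome 1 at 93055685 to 93056280 inside Kif1a (1.86, SE 0.18), chromosome 9 at 72809455 to 72858949 inside Prtg (1.85, SE 0.26) and chromosome 8 at 33669153 to 33685702 inside Gsr (1.81, SE 0.33). They were well above background on 2, 2 and 1 of 3 Sham arrays. With the slide as a block 9 of these 18 probes stayed called. Without 1 array 3 stayed called without Sham-1, 6 without Sham-2, 13 without Sham-3, 8 without DJB-1, 4 without DJB-2 and 15 without DJB-3.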

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

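No result was singled out by a rule on samples far from their group, which was not applied to groups of 3, and 3 patterns were weighed. Of the tests below, those on the choice of scaling, on the share of adipocytes and on muscle and liver tissue were chosen only after the result was seen, and the test that removed a trend with signal was designed after the split of calls by signal was known.

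Called genes were mostly lower while called interval-named probes were mostly higher (886 against 340). The direction of the latter depended on the threshold. At an unadjusted p under 0.05, 6931 of 9183 were higher, but in the looser set, which also asks for a 2-fold difference, interval-named probes were mostly lower as well (190 higher, 597 lower), adjusted within their type 14 were lower and limma called 0 higher, and without any 1 array lower calls outnumbered higher ones among them (302 higher against 584 lower without DJB-3). A signal-dependent offset of the dimmer DJB arrays might give such a split, since the share of lower genes among the called was 92.3% among dim genes, 84.1% among those of middle signal and 62.0% among bright ones (3 groups of equal size). With each array's trend with signal removed, 81.7% of called genes were still lower. Over all probes, however, 2966 were then called higher and 3010 lower, against 1830 and 3137 before. Among interval-named probes 1519 were then called higher and 262 lower. Interval-named probes exceeded mRNA probes of matched signal by 0.216 (log2), with all 20 signal bins above 0. An offset that moves all probes of an array alike at a given signal therefore explains neither the excess of lower called genes nor the higher values of interval-named probes. For the excess of lower calls over all probes, which was nearly lost with the trend removed, such an offset stays open. The bins share the same 6 arrays, and the excess was 0.349 in the dimmest bin and 0.136 in the brightest. The split by signal was not counted again after the trend was removed, so other effects of low signal stay open. Over 6 scalings the lowest share of lower genes among the called was 71.1%, so the choice of scaling does not explain the excess of lower called genes. At an unadjusted p under 0.05 in limma's test, however, median scaling put 3566 of 6509 genes higher against 2455 of 6142 in the original scaling. An effect of the bypass, or of anything that went with it, remains a hypothesis that no test here separates from other differences between these samples.

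Adipocyte lists were lower and the macrophage list was higher by camera with its preset correlation, but with an estimated correlation no list was past the threshold (adjusted p = 0.510 for the macrophage and endothelial lists and 0.525 for the mature adipocyte list). A lower share of adipocytes in the DJB samples may lower adipocyte genes, but would raise markers of the other cells of the tissue together. Endothelial markers were instead lower (median -0.475, quartiles -0.847 to -0.276). Their array scores were 0.317, 0.185 and 0.328 in Sham and -0.558, -0.343 and -0.009 in DJB. Their median was -0.679 on slide 1 and -0.119 on slide 2. A lower adipocyte share alone therefore does not explain the endothelial values. Whether it explains the adipocyte and macrophage lists stays open, since another change may have lowered endothelial markers. Lists of other cells went both ways, such as neutrophil and mast cell (0.775) and mesothelial (-1.599). Fewer adipocytes together with other changes in the mix of cells, and a change within adipocytes or macrophages, could not be told apart.

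Genes of skeletal muscle and liver were among the largest falls. Pieces of either tissue in the Sham samples could give this. The skeletal muscle median was -0.197 over the brightest probe of each gene, where 8 of 15 genes changed by less than 0.5 (log2). Over the lowest probe of each gene it was -1.489, a choice that can only lower the median. The probes of a gene differed by over 0.5 in 8 of the 15 genes, so muscle in the samples could be neither shown nor excluded. Of the 14 liver genes 2 were well above background on all arrays and higher in DJB by over 0.3 (log2), and of these 1 (Ahsg, 1.25, SE 0.517, adjusted p = 0.178) by over 2 standard errors. Its groups overlapped. This also leaves liver in the samples open. An effect of the bypass on these genes was not separated from either.

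The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a test. Except in the real split, each side holds Sham and DJB arrays. A difference between Sham and DJB of any cause then adds to the spread within a side. Part of that difference also stays between the sides. The counts of the other splits are therefore no baseline for chance, and no conclusion is drawn from the ranking below. Every split other than the real one still gave list calls, from 3 to 17, by camera at the preset correlation. The real split gave the highest count in each case (1 of the 10 splits): 4967 called probes against at most 0 in any other split by limma's test, 5980 probes in the looser set against 1897, 2165 called probes other than mRNA against 0, and 22 lists against 17.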

How the results depend on the processing

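Counts of calls moved widely, and 16 of the 22 called lists stayed past the threshold under all alternatives but an estimated correlation and fry. Over all 22, the adjusted p ran from 6.88e-08 to 0.194 without these 2, and to 0.634 with them. The tests of slide 1 alone were chosen after seeing the data; where no cause is given, the cause was not tested. Signal over background limited dim probes: 62.6% to 68.8% of probes were well above it.

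Counts are given higher then lower; they were 1830 and 3137 for probes, 867 and 5113 for the looser set, 1074 and 1091 for probes other than mRNA, 886 and 340 for interval-named probes, 257 and 1117 for genes, and 7 and 15 for lists. Normexp gave 7011 and 4901 probes, 211 and 1929 looser, 4513 higher non-mRNA, 3293 higher interval-named probes, 1028 and 399 NONCODE, 156 and 170 Ensembl, 35 and 71 RefSeq non-coding, and 821 and 2190 genes. Median scaling gave 2026 lower probes, 1525 looser higher, 660 lower non-mRNA and 177 lower interval-named probes, and an all-probe median of 0.186 in place of 0.080. Lower calls were 63.2% of probes, 41.1% with normexp and 51.5% with median scaling and 50.2% with a trended prior; of genes they were 81.3%, 71.1% with median scaling and 66.3% with a trended prior. Without a filter there were 73 and 576 probes, 1684 looser higher, 48 and 203 non-mRNA, 22 and 47 interval-named, and 10 and 205 genes. Probes above background on all 6 arrays gave 3485, 2012, 1704 and 495 higher probes, non-mRNA, interval-named and genes, and on all 3 of a group 2824, 1642, 1355 and 412. A trended robust prior gave 5292 and 5329 probes, 2669 and 1729 non-mRNA, 2265 and 636 interval-named, and 980 and 1927 genes; array weights gave 3077 and 4807, 1796 and 1810, 1407 and 699, and 473 higher genes. Adjusted within probe type there were 65 and 459 non-mRNA, and 0 and 14 interval-named probes (limma; 6931 higher with an unadjusted p under 0.05).

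The slide as a block gave 88 and 619 probes, 48 and 200 non-mRNA, 34 and 44 interval-named (lower calls in excess, as without a filter and within probe type), and 12 and 223 genes. The slides are balanced, so the block leaves each difference as it is. Slide 1 alone, with 2 against 2 arrays, gave 0 calls by limma in either direction for probes, non-mRNA, interval-named and genes (21781 probes with an unadjusted p under 0.05) and 1483 looser higher; slide 2 has 1 array per group and no test. The signs of 31 lists held on slide 1 and of 29 on slide 2. On slide 2 the signs changed for the incretin and bile acid receptor (0.031), acinar (0.182) and inflammatory (-0.225) lists. With the replicate number as a block limma called 0 probes, non-mRNA, interval-named and genes in either direction (21436 probes with an unadjusted p under 0.05). The samples share only a number. After each group's mean was subtracted per probe, the deviations of arrays with the same number correlated at -0.185, -0.117 and -0.295. By these deviations, no array correlated best with the array of its own number in the other group. Camera with an estimated correlation called 0 and 0 lists (0 and 1 with an unadjusted p under 0.05), and fry 0 and 5 (5 and 12).

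Without each array the counts ranged from 1 to 790 and 118 to 3181 for probes, 695 to 1282 and 3888 to 6243 in the looser set, 0 to 481 and 33 to 1187 for non-mRNA, 0 to 302 and 8 to 584 for interval-named probes, 0 to 124 and 43 to 1164 for genes (0 without DJB-2, where 1750 had an unadjusted p under 0.05), and 6 to 8 and 14 to 16 for lists. Values that changed sign, none of them called, were the RefSeq non-coding median (-0.081; 0.058 with normexp, 0.024 with median scaling), the Ensembl median (-0.027; 0.112 with normexp, 0.044 with quantile normalization, 0.079 with median scaling, 0.041 with the authors' values, 0.056 without a filter, 0.015 with array weights, 0.045 on slide 1, 0.001 without Sham-3, 0.056 without DJB-3), the NONCODE median (0.063; -0.007 without DJB-2), the adipocyte progenitor list (-0.013 with normexp, -0.018 with quantile normalization, -0.024 with the authors' values), the hypoxia list (-0.073 with the mean of probes, by the test's direction; 0.015 without DJB-2), the inflammatory list (-0.083 without DJB-2), acinar (-1.107 to 0.087, positive without Sham-1), interferon (-0.605 to 0.188, positive without DJB-2; 0.115 on slide 1), Ucp1 (-1.945 to 0.629, without Sham-1), Pnpla2 (-0.414 to 0.021, without DJB-1) and Tnf (-0.593 to 0.093; 0.018 without Sham-2, 0.093 without Sham-3, 0.044 without DJB-3, 0.222 on slide 1). Of lists, those past the threshold or lost elsewhere were oxidative phosphorylation (gained) and liver (lost) with normexp, oxidative phosphorylation (gained), endoplasmic reticulum stress and extracellular matrix (lost) with quantile normalization and the authors' values, glucocorticoid with median scaling and slide 1 (lost), insulin with the mean of probes (lost), and acinar on slide 1 (gained).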

Other observations

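The genes around the called interval-named probes were compared after the values had been seen. Only probes inside exactly 1 gene of the gene table, on either strand, were used, and only where that gene was tested. The 852 such probes called higher lay in 399 genes with a median log2 difference of 0.488 (56 rose, 1 fell and 342 were not called). The 316 called lower lay in 166 genes with a median of -0.994 (97 fell, none rose and 69 were not called). The 6299 genes around all 30393 tested probes of this kind had a median of 0.032 (79 rose, 340 fell and 5880 were not called). Genes with many such probes were Stxbp5 (31 of 42 called higher, gene difference 0.876, adjusted p = 0.0355), Atp6v1h, of the vacuolar proton pump (23 of 25, 0.64, 0.0573), and Nsf, of vesicle fusion (18 of 21, 0.726, 0.0506), and on the lower side Dmd, which encodes dystrophin (9 of 24, -1.274, 0.0114), and Ptprk (8 of 17, -1.529, 0.0365).

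Scores of some tissue lists varied between arrays of a group. The acinar score was 1.676 on Sham-1, -0.713 on Sham-2, 0.191 on Sham-3, -0.728 on DJB-1, 0.522 on DJB-2 and -0.661 on DJB-3. The epididymis and testis score was 1.172, 1.331 and -1.178 on the Sham arrays and -0.855, 0.029 and -0.957 on the DJB arrays.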
